A study of Mus musculus with 8 samples.

How the data were processed

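RNA-seq was deposited for 8 spinal cord samples of mice, collected 7 days after spinal cord injury. Per the labels, 4 samples came from mice of genotype Tia1f/f, called control here, and 4 from Tia1Nestin-CKO mice, called CKO here. Each sample is named by its group and the replicate number in its title. The labels number the samples but do not state that each came from a separate mouse, and where samples shared a mouse the p-values would measure only the spread between samples. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra RNA kit for Illumina.

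The authors deposited a table of read counts per gene, whole numbers that were not normalized, for 54532 Ensembl mouse genes with 1 column per library. The submitters' processing notes name CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, without giving their roles. The same notes name a human genome build. The deposited tables hold mouse gene identifiers, and of the 54495 identifiers shared with GENCODE M21 on GRCm38, 53585 (98.3%) have the same start and end there. Coordinates are therefore given as in the deposited tables, on GRCm38. The annotation release, the handling of reads with several matches and the use of strand are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies could thus not be told apart.

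The authors also deposited FPKM values for the same genes and libraries. Each deposited FPKM value of genes over 200 counts equals the count divided by the listed gene length and by 1 constant per library, within a relative deviation of 5.1e-15. That constant was 0.971 to 1.03 of the library's total count. FPKM served only as an alternative to counts.

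Total counts ran from 14752733 to 17802884 per library. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr by group with a minimum count of 10 and a minimum total count of 15, which left 16537 genes. Libraries were scaled by TMM factors, and CKO was tested against control with edgeR's quasi-likelihood F test with robust=TRUE and genotype as the only term. The standard error of a log2 fold change was taken as its size divided by the square root of F, and intervals are 95%. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05 and no fold minimum. Normalized CPM are counts per 1000000 after TMM scaling. Tia1, Tial1 and Nes were also compared by an exact two-sided permutation test of normalized CPM over 70 assignments.

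Lists of genes, 36 in number, were fixed before the data were examined, for cell types, injury responses and functions of TIA1. Of their 681 symbols, 2 were matched through synonyms and 1 was not matched. Lists with at least 3 members among the genes tested, 35 in number, were tested with camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and adjusted over the lists. The list of adipose tissue had fewer members and was not tested. Camera with an estimated correlation and fry's directional p were alternatives. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. A list's level in a library is the mean of its members' log2 CPM, each relative to that gene's mean over the 8 libraries.

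The genes named in the text were chosen by a rule also fixed before the data were examined. Tia1, Tial1 and Nes were always named. Since no gene passed the threshold, the 5 genes of smallest unadjusted p in each direction were named, as genes that did not pass. In each list past the camera threshold, up to 4 members with the smallest p in the list's direction were named, except some that are not reported here. The most abundant genes and the sex-linked Ddx3y and Xist were named to describe the samples, and other genes outside this rule were chosen after their values were seen.

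Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter, a stricter filter of at least 1 CPM in at least 4 libraries, each library left out in turn, the replicate number as a block, robust=FALSE, protein-coding genes, a fold minimum, the DESeq2 1.42.0 Wald test, limma-voom, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1). Fits without libraries in doubt, limma-voom with library weights, DESeq2 on the genes kept by filterByExpr, and removal of a trend on GC content and length were added after the data were seen. GC content and length were those of each gene's longest transcript in GENCODE M21, which covered 99.9% of the genes tested. No GC correction was used in the main test.

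The count test was tested on simulated data for CKO against control, with 4 libraries per group and the means, library totals and spread of the real libraries. Among 16275 simulated genes, it recovered 2.0% of 50 genes changed 1.5-fold, 38.0% of 50 changed 2-fold, 75.5% of 49 changed 3-fold and 89.6% of 48 changed 4-fold. Of its 106 calls, 6 were false. The simulated genes were drawn independently of each other and without a library that stands apart. Of the unchanged simulated genes, 5.16% had an unadjusted edgeR p under 0.05, against 1.42% of all genes in the real test. Recovery in the real libraries may therefore be lower. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.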

Results

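The transcriptome of injured mouse spinal cord was measured by RNA-seq 7 days after injury in 4 samples of Tia1f/f mice, the control group, and 4 samples of Tia1Nestin-CKO mice, the CKO group. TIA1 is an RNA-binding protein of stress granules, and the genotype name is that of a conditional knockout driven by Nestin, a gene of neural stem and progenitor cells. The comparison asks how the injured cord differs in gene expression when Tia1 is removed from that lineage. The deposited read counts summed to 14752733 in the library labelled control 1 and to 16189372 to 17802884 in the others. By the mean of the 8 libraries, the 2 most abundant transcripts were those of Mbp, a protein of central myelin, at 19339 ± 2984 CPM (SD, n = 4) in control and 22227 ± 1575 CPM in CKO, and of the ferritin heavy chain gene Fth1, at 15067 ± 2316 and 19051 ± 2535 CPM. The mitochondrial gene mt-Co1, at 17972 ± 4376 and 15776 ± 4065 CPM, was above Fth1 in control. Apoe, Gfap, Spp1 and Lyz2, genes of reactive astrocytes and of macrophages, were also among the 10 most abundant genes. Gfap, the intermediate filament of astrocytes, stood at 10491 ± 1890 CPM (SD, n = 4) in control and 10206 ± 1850 CPM in CKO. All 8 libraries had counts of the Y-linked gene Ddx3y, from 1031 to 2031, and 0 to 2 counts of Xist, so expression was of the male type in each.

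The libraries did not part by genotype. The first principal component of log2 CPM, with 41.6% of the variance, set the library labelled control 1 at -94.97 against 5.73 to 21.51 in the other 7. In that library 18884 genes had counts, against 22434 to 23414 in the others, and 2729 of the tested genes (16.5%) lay over 1 log2 unit from the median of the other libraries, against 459 to 807 in the others. The second component, with 18.8%, set the libraries labelled control 3 and CKO 4 at -38.73 and -38.14, and these libraries had the highest correlation of any pair (r = 0.981 across genes, which are not independent replicates). Mitochondrial genes took 6.97% of counts in the library labelled control 1 and 3.16% to 6.37% in the others.

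**Figure D1:**
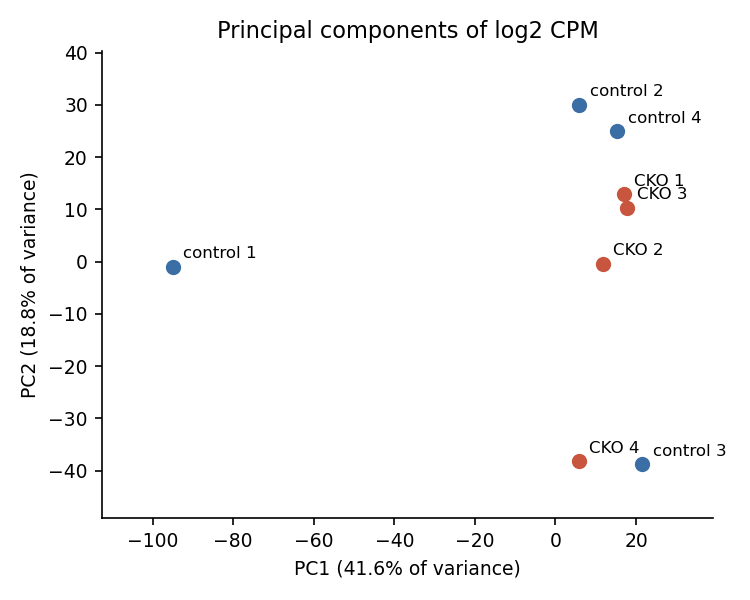
Principal components 1 and 2 of log2 CPM over 16537 genes, in the components' own units, with 1 point per library (blue, control; red, CKO). The library labelled control 1 lies at -94.97 on PC1, and the libraries labelled control 3 and CKO 4 lie together at the bottom of PC2.

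Tia1, the targeted gene (ENSMUSG00000071337, chromosome 6, 86404219 to 86433405, plus strand, GRCm38), was read in all 8 libraries. Its raw counts were 602, 411, 564 and 603 in the libraries labelled control 1 to 4, and 417, 434, 399 and 570 in those labelled CKO 1 to 4. Normalized, these were 41.9, 24.4, 31.3 and 34.2 CPM in control and 23.4, 27.8, 24.0 and 32.1 CPM in CKO. The means were 32.9 ± 7.21 CPM (SD, n = 4) in control and 26.9 ± 4.01 CPM (SD, n = 4) in CKO, a difference of -18.5% that did not exceed the spread between libraries. The exact two-sided permutation test gave p = 0.20 over 70 assignments. The log2 fold change was -0.29 (SE 0.19, 95% interval -0.71 to 0.12), with an edgeR unadjusted p = 0.144 and adjusted p = 1.00. The library labelled control 2 had less Tia1 than 2 of the CKO libraries, and the library labelled CKO 4 had more than 2 of the control libraries, so these 2 libraries lay nearer the other group. Without the library labelled control 2 the log2 fold change was -0.41, with an unadjusted edgeR p of 0.040. That library had the lowest Tia1 of its group, so its omission must enlarge the difference, and this p is no support for a fall. Without the library labelled control 1, which stands apart from the others, the log2 fold change was -0.16, with an unadjusted edgeR p of 0.367. Gene counts cover all exons, and the deleted exons are not given in the sources used here, so a transcript lacking them would still be counted in part. The samples also hold cells outside the Nestin lineage, in which the gene would be intact. The level of Tia1 alone can therefore not show that a label is wrong.

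The paralog Tial1, which encodes the related protein TIAR, had 49.6 ± 2.27 CPM (SD, n = 4) in control and 48.4 ± 2.85 CPM in CKO, a log2 difference of -0.04 (SE 0.12, 95% interval -0.30 to 0.23). The exact permutation test gave p = 0.457. Nes, the gene of Nestin itself, had 76.4 ± 19.5 CPM (SD, n = 4) in control and 72.4 ± 12.6 CPM in CKO, a log2 difference of -0.08 (SE 0.20, 95% interval -0.53 to 0.37), with an exact permutation p of 0.714. With each library left out in turn, Nes ran from -0.22 to 0.05.

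**Figure D2:**
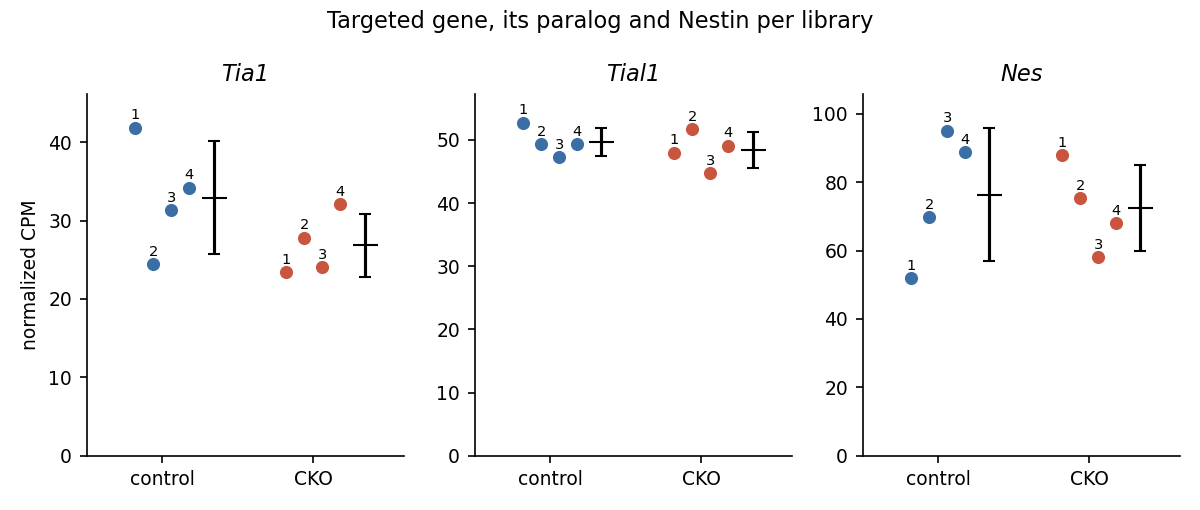
Normalized CPM of Tia1, Tial1 and Nes in each library, numbered by replicate (blue, control; red, CKO), with the group mean and SD in black (n = 4). Tia1 in the library labelled control 2 (24.4 CPM) lies among the CKO libraries, and in that labelled CKO 4 (32.1 CPM) among the control libraries.

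No gene passed an adjusted p of 0.05 between CKO and control. Of 16537 genes tested with edgeR's quasi-likelihood test, 234 had an unadjusted p under 0.05, 82 higher and 152 lower in CKO, against 827 that chance alone would give, and the smallest adjusted p was 1.00. The DESeq2 Wald test called 1 gene, Saa3, both over the 28868 genes for which it gave an adjusted p and over the genes kept for edgeR, an addition made after the data were seen. Limma-voom and limma-trend called 0. Groups did not overlap for 197 genes (1.19% of those tested), where chance gives 2.86%. Directions in this comparison rest on the labels, and Tia1 in the libraries labelled control 2 and CKO 4 lay nearer the other group. Without those 2 libraries, a choice made after the data were seen, 0 genes passed and 252 had an unadjusted p under 0.05. The libraries' spread, a biological coefficient of variation of 0.27, left a median interval of ±0.41 log2 units for the 10604 genes of at least 10 CPM.

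Among genes higher in CKO, none of which passed, the smallest unadjusted p belonged to Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase gene of inflamed tissue. It had 3.14 ± 1.12 CPM (SD, n = 4) in control and 13.3 ± 7.68 CPM in CKO, a log2 fold change of 2.07 (SE 0.44), higher in 4 of 4 CKO libraries than in any control library. The edgeR adjusted p of Saa3 was 1.00, and DESeq2 gave an adjusted p of 0.021. Hspb1, a small heat shock protein gene found in reactive astrocytes, had 195 ± 26.0 CPM in control and 307 ± 62.8 CPM in CKO, a log2 fold change of 0.65 (SE 0.17). Zbtb16, which encodes the transcription factor PLZF, had a log2 fold change of 1.04 (SE 0.26) from 7.66 ± 1.51 CPM. Mlph, which encodes melanophilin, had one of 0.76 (SE 0.22) from 5.34 ± 1.05 CPM, and Gm10705 one of 1.41 (SE 0.39) from 4.03 ± 1.73 CPM.

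Among genes lower in CKO, which also did not pass, the long noncoding RNAs Meg3 and Malat1 stood out by level. Meg3 had 84.9 ± 36.3 CPM (SD, n = 4) in control and 40.8 ± 2.97 CPM in CKO, a log2 fold change of -1.06 (SE 0.27). Malat1 had 46.5 ± 21.6 CPM and 23.3 ± 2.75 CPM, a log2 fold change of -1.0 (SE 0.26), with 78.9 CPM in the library labelled control 4 against 34.96 to 36.9 CPM in the other control libraries, and without that library the log2 fold change was -0.62. The mitochondrial leucine tRNA gene mt-Tl2 had 11 to 47 counts per control library and 2 to 6 per CKO library, a log2 fold change of -2.88 (SE 0.56). Ncmap, a gene of peripheral myelin, had 12.6 ± 1.74 CPM in control and 7.70 ± 1.46 CPM in CKO, and the sodium-activated potassium channel gene Kcnt1 had 15.96 ± 3.14 and 10.2 ± 1.06 CPM. All 5 genes were lower in each CKO library than in any control library.

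**Figure D3:**
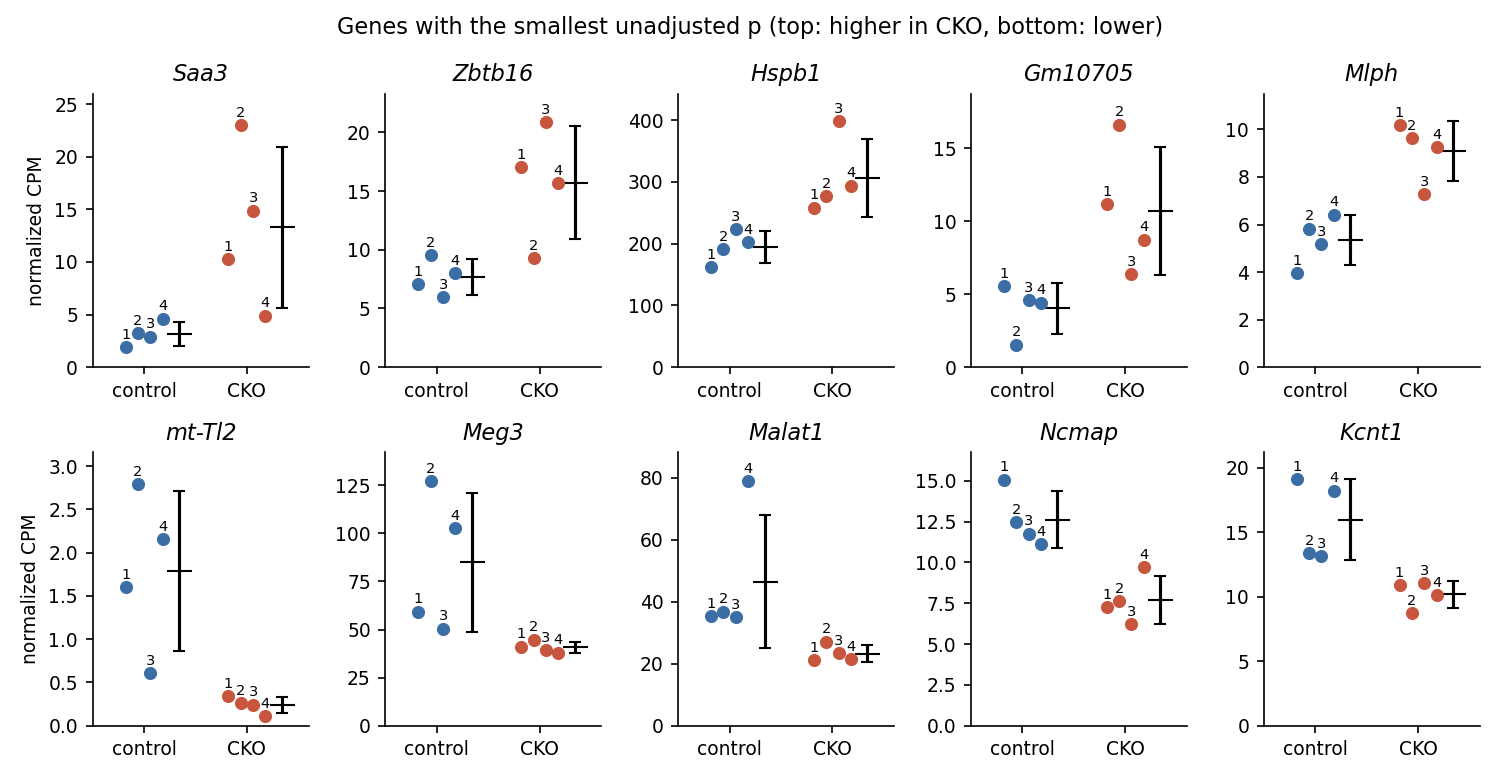
Normalized CPM per library of the 10 genes with the smallest unadjusted p, numbered by replicate (blue, control; red, CKO), with the group mean and SD in black (n = 4). Saa3 had 3.14 CPM in control and 13.3 CPM in CKO, Meg3 84.9 and 40.8 CPM, and none of the 10 passed after adjustment.

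Of 35 fixed lists tested with camera at the preset correlation, 12 passed the threshold, 6 higher and 6 lower in CKO. With an estimated correlation none of these 12 calls held, each with an adjusted p = 0.797 with an estimated correlation. Fry, which asks whether a list's genes move one way without comparing them with other genes, gave 0 lists, with an adjusted p = 0.922 for each of the 12. No member of any list passed over all genes, and 1 member, Ncmap, passed adjusted over the list alone. These directions too rest on the labels, and Tia1 in the libraries labelled control 2 and CKO 4 lay nearer the other group. Without both libraries, 7 lists passed. Leaving out the library labelled control 2 alone gave 7 lists, and leaving out that labelled control 3 gave 19. Over the 35 splits of the 8 libraries into groups of 4, a test chosen after the results were seen, the median was 11 lists.

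Lists of inflammation and of reactive glia were among the 6 higher ones. All 14 neutrophil genes had a higher mean in CKO, with a median log2 fold change of 0.65 (camera adjusted p = 0.00010). They included the granule genes Mpo, at 7.97 ± 1.45 CPM in control and 13.1 ± 4.80 CPM in CKO, and Ltf, at 60.2 ± 18.9 and 113 ± 85.3 CPM, as well as Mmp9 (log2 fold change 0.69, SE 0.30) and Il1r2 (0.88, SE 0.40). The level of this list was 1.22 log2 units above the mean in the library labelled CKO 2, where Ltf reached 241 CPM. The erythrocyte list also stood highest in that library, at 1.23. Without that library the camera adjusted p of the neutrophil list was 0.115 and its mean difference 0.16 instead of 0.48. The log2 fold changes of Ltf, Mmp9 and Mpo were then 0.23, 0.37 and 0.44 instead of 0.91, 0.69 and 0.72. The list's mean difference was 0.30 without the library labelled control 4, where its level was -0.80. The libraries labelled CKO 3 (-0.33) and CKO 4 (-0.13) stood below those labelled control 1 (-0.12), control 2 (0.06) and control 3 (-0.10). Of 36 reactive astrocyte genes 26 were higher, with a median of 0.13 (camera adjusted p = 0.0033). The 10 lower ones included Gfap and Nes, with log2 fold changes of -0.04 and -0.08. Besides Hspb1 the higher ones included the lipocalin Lcn2, at 47.3 ± 11.8 and 99.0 ± 46.3 CPM, with 164 CPM in the library labelled CKO 2. Others were Serpina3n, at 480 ± 135 and 737 ± 119 CPM, and Fkbp5, a gene induced by glucocorticoids, at 79.5 ± 22.8 and 134 ± 36.4 CPM. That call was lost without the library labelled control 2 (adjusted p = 0.465, mean difference 0.079 instead of 0.172) or CKO 1 (0.052), and Lcn2 went from a log2 fold change of 1.07 to 0.71 without that labelled CKO 2. Of 24 genes of inflammatory cytokines and the inflammasome 16 were higher, with a median of 0.06 (camera adjusted p = 0.040). Tnf had 1.04 ± 0.81 and 2.25 ± 0.75 CPM, Ptgs2 5.89 ± 3.58 and 9.07 ± 3.01 CPM, Il1b a log2 fold change of 0.57 (SE 0.36) and Ccl5 one of 0.51 (SE 0.37). Ccl5 fell to 0.30 without the library labelled CKO 1, and Ptgs2, at 0.62, was 0.35, 0.41 and 1.07 without those labelled control 4, CKO 4 and control 3. The list's call was lost without the library labelled control 2 (adjusted p = 0.895, mean difference 0.120 instead of 0.231), control 4 (0.249), CKO 1 (0.164) or CKO 2 (0.116), without members shared between lists (0.066), under the stricter filter (0.081), with no filter (0.060) and with the replicate block (0.064).

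The other 3 higher lists were of dividing cells, ribosomes and vessels. All 26 proliferation genes had a higher mean in CKO, with a median log2 fold change of 0.23 (camera adjusted p = 0.00036). The mitotic genes Aurka (log2 fold change 0.45, SE 0.24), Cdc20 (0.42, SE 0.23), Tpx2 (0.40, SE 0.27) and Ccnb2 (0.31, SE 0.23) had the smallest p among them. This call was lost without the library labelled control 2 (adjusted p = 0.278) or CKO 1 (0.156), where the mean difference of 0.23 was 0.12 and 0.11. It was 0.14 without that labelled control 1, and 0.37 and 0.39 without those labelled control 3 and CKO 3. Tpx2 was 0.24 without that labelled control 1 and 0.23 without CKO 1, and Ccnb2 0.18 without control 2 and 0.48 without control 3. The level of the proliferation list ran from -0.44 to 0.28 in control libraries and from -0.36 to 0.48 in CKO libraries, so the groups overlapped. The estimated correlation between its genes was 0.76, so the 26 genes did not vary independently. Of 28 ribosomal protein genes 27 were higher, with a median of 0.18 (camera adjusted p = 6.9e-06). Rps20 had 541 ± 90.8 CPM in control and 660 ± 49.1 CPM in CKO, and Rpl10a, Rpl14 and Rpl32 had log2 fold changes of 0.29, 0.22 and 0.40. The level of this list was -0.57 in the library labelled control 1 and -0.04 to 0.16 in the other 7, and without that library the mean difference was 0.097 instead of 0.246, and Rps20, Rpl10a, Rpl14 and Rpl32 had log2 fold changes of 0.17, 0.15, 0.14 and 0.17, the first from 0.29. The call held with each library left out in turn, with adjusted p of at most 0.00075, but was lost with an estimated correlation (0.797), which was 0.39 for this list. Of 21 endothelial genes 15 were higher, with a median of 0.15 (camera adjusted p = 0.016). Vwf, the von Willebrand factor, had 39.5 ± 15.3 and 59.6 ± 6.42 CPM, and Ly6c1, the lipid transporter Mfsd2a and the transcription factor Erg had log2 fold changes of 0.43, 0.45 and 0.74. The endothelial level was -0.57 in the library labelled control 1, without which the adjusted p was 0.278, the mean difference 0.106 instead of 0.253, Erg 0.44 and Vwf 0.39 instead of 0.59. The list's adjusted p was 0.253 without the library labelled control 2.

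The 6 lower lists included those of synapses and of neurons. Of 30 synapse and neurotransmitter receptor genes 28 had a lower mean in CKO, with a median log2 fold change of -0.29 (camera adjusted p = 9.1e-06). The glutamate receptor subunit gene Gria2 had 31.1 ± 10.2 CPM in control and 19.0 ± 4.08 CPM in CKO, and the glycine receptor subunit gene Glrb 117 ± 62.4 and 72.9 ± 9.51 CPM. Of 20 neuronal genes 18 were lower, with a median of -0.21 (camera adjusted p = 0.024). Slc5a7, the choline transporter of motor and other cholinergic neurons, had 13.5 ± 9.10 and 5.79 ± 2.82 CPM, Nefl 381 ± 198 and 272 ± 35.3 CPM, Snap25 579 ± 285 and 412 ± 53.2 CPM, and Slc17a6 49.1 ± 23.01 and 34.9 ± 7.67 CPM. The library labelled control 2 stood at 0.75 for the neuronal list and 0.65 for the synapse list. Without it the neuronal list's mean difference was 0.035, in the other direction (adjusted p = 0.655), and the synapse list's adjusted p was 0.105, with a mean difference of -0.120 instead of -0.290. The log2 fold changes of Nefl, Snap25 and Slc17a6, each -0.49 with all libraries, were then -0.07, -0.15 and -0.18. Without the library labelled control 1, Glrb went from -0.68 to -0.33 and Slc5a7 from -1.22 to -0.77. The neuronal call was also lost without the library labelled CKO 1 (0.058) or CKO 4 (0.316, with a mean difference of -0.098 instead of -0.185) and with no filter (0.069).

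Another 2 of the 6 lower lists, which passed camera at the preset correlation only, were of extracellular inhibitors and of peripheral myelin. Of 21 genes of chondroitin sulphate proteoglycans and growth inhibitors 15 were lower, with a median log2 fold change of -0.19 (camera adjusted p = 0.028). The myelin inhibitor gene Omg had 66.1 ± 32.6 CPM in control and 43.8 ± 10.3 CPM in CKO, Ptprz1 96.6 ± 46.1 and 68.0 ± 10.8 CPM, the xylosyltransferase gene Xylt1 37.3 ± 7.02 and 29.6 ± 2.68 CPM, and Sema3a a log2 fold change of -0.43 (SE 0.26). That call was lost without the library labelled control 1 (adjusted p = 0.311, mean difference -0.085 instead of -0.157), control 4 (0.309), CKO 1 (0.067) or CKO 4 (0.222), and with no filter (0.066). Without the library labelled control 1 the log2 fold change of Ptprz1 was -0.16 instead of -0.51, that of Sema3a -0.14, that of Omg -0.32 instead of -0.59 and that of Xylt1 -0.21 instead of -0.33. Of 11 Schwann cell and peripheral myelin genes 10 were lower, with a median of -0.25 (camera adjusted p = 0.00086), and the call held with each library left out in turn (adjusted p of at most 0.039), but not with an estimated correlation (0.797). The list's level was -0.50 in the library labelled CKO 3, without which the mean difference was -0.157 instead of -0.278, while that labelled CKO 4 (0.147) stood above those labelled control 2 (-0.013) and control 4 (0.050). Ncmap had a log2 fold change of -0.71 (SE 0.20) and an edgeR adjusted p of 0.047 adjusted over the list alone, against 1.00 over all genes. Prx, the periaxin gene, had 52.3 ± 9.84 and 37.6 ± 11.8 CPM, and Mal2 and Pmp2 had log2 fold changes of -0.57 (SE 0.30) and -0.98 (SE 0.64), the latter from 0.86 ± 0.54 CPM. Without the library labelled control 1 these 2 were -0.28 and -0.62, and without that labelled CKO 3, Prx went from -0.48 to -0.27.

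Of 28 interferon response genes 19 were lower, with a median log2 fold change of -0.16 (camera adjusted p = 0.013). Ifit1 had 24.4 ± 9.08 CPM in control and 12.9 ± 5.85 CPM in CKO, and Rsad2, Mx1 and Oasl2, antiviral genes induced by interferon, had log2 fold changes of -0.61 (SE 0.27), -0.83 (SE 0.42) and -0.34 (SE 0.25). The interferon list stood at 0.58 in the library labelled CKO 1 and -0.62 in that labelled CKO 2, so that the highest and the lowest level were both in the CKO group. The call was lost without the library labelled CKO 2 (adjusted p = 0.820), CKO 4 (0.060), control 1 (0.359) or control 3 (0.075), and the mean difference of -0.178 was -0.0011 without that labelled CKO 2, -0.077 without control 1 and -0.40 without CKO 1. Oasl2 was -0.13 without the library labelled CKO 2, and Mx1 -0.43 without that labelled control 1. All 13 mitochondrially encoded mRNAs had a lower mean in CKO, with a median of -0.48 (camera adjusted p = 0.00096). mt-Co3 had 232 ± 211 and 117 ± 63.7 CPM, with 544 CPM in the library labelled control 2 against 90.2 to 168 CPM in the other control libraries, and its log2 fold change was -0.99 with that library and -0.12 without it. mt-Co2 had 212 ± 66.8 and 152 ± 63.4 CPM, and mt-Nd4l and mt-Nd3 had log2 fold changes of -1.61 (SE 0.52) and -0.57 (SE 0.39). For mt-Nd4l, the libraries labelled control 1 and control 4 had 59.6 and 63.0 CPM. Those labelled control 2 and control 3 had 15.4 and 11.2 CPM, within the 8.07 to 17.7 CPM of the CKO libraries. mt-Nd3 was -0.29, -0.37 and -0.37 without the libraries labelled control 2, control 1 and CKO 3, and mt-Co2 went from -0.48 to -0.81 without that labelled CKO 2. mt-Nd4l shares its end with mt-Nd4, and mitochondrial genes have near-identical nuclear copies, so their counts are uncertain. Their level was 0.75 in the library labelled control 1, without which the adjusted p was 0.241 and the mean difference -0.26 instead of -0.44, and -0.80 in that labelled CKO 3, without which they were 0.130 and -0.24. The mean difference was -0.65 without the library labelled CKO 2.

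**Figure D4:**
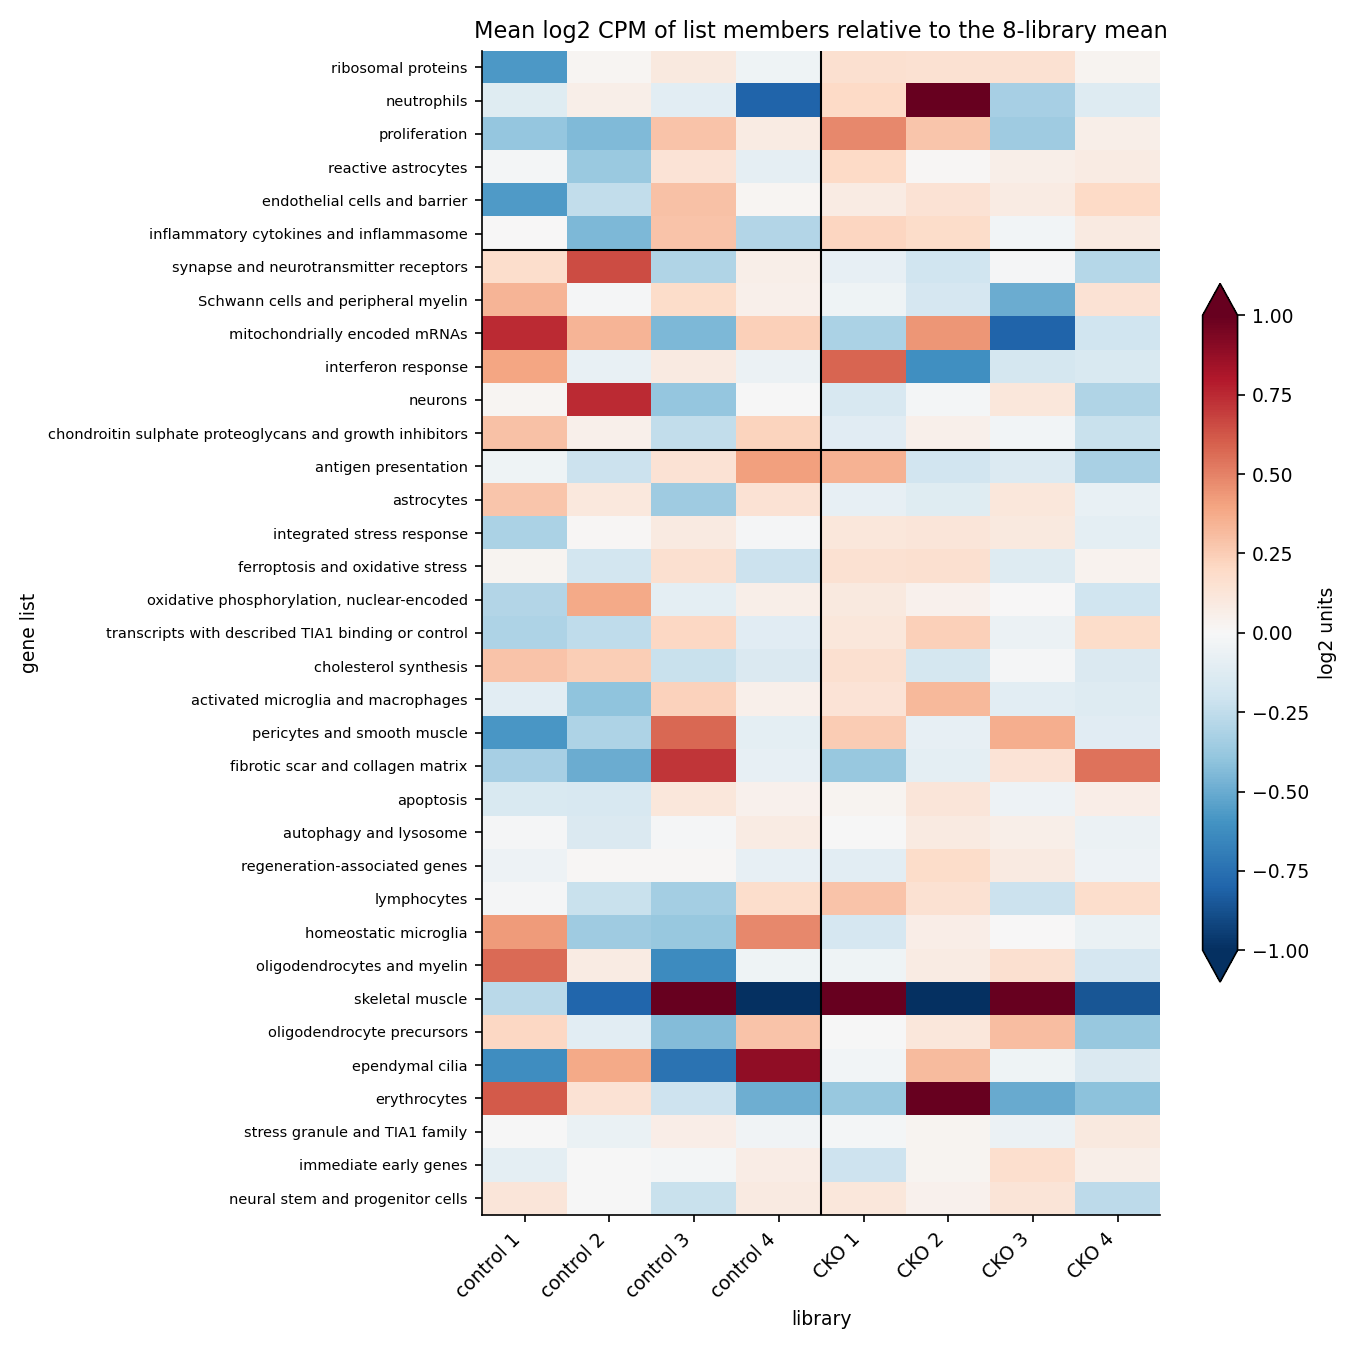
Mean log2 CPM of the members of 35 gene lists in each library, relative to the mean of the 8 libraries, in log2 units (red above, blue below, saturating at -1 and 1). The top 6 lists passed camera as higher in CKO, the next 6 as lower, and the remaining 23 did not pass; the neuronal list is highest in the library labelled control 2 (0.75) and the neutrophil list in that labelled CKO 2 (1.22).

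The remaining 23 lists did not pass camera, with adjusted p of 0.150 and above. They included the stress granule and TIA1 family, of whose 28 genes 13 were higher and 15 lower in CKO, with a median log2 fold change of -0.01. G3bp1, a core gene of stress granules, had 104 CPM in control and 109 CPM in CKO, and Caprin1 295 and 297 CPM, as examples chosen after their values were seen. Of 9 transcripts with described binding or control by TIA1, 5 were higher, with a median of 0.08, and of 20 genes of the integrated stress response 14 were higher, with a median of 0.08. Lists of resident glia had medians of -0.17 for astrocytes, -0.02 for oligodendrocytes and myelin, 0.06 for oligodendrocyte precursors, -0.09 for homeostatic microglia and -0.04 for neural stem and progenitor cells. Activated microglia and macrophages had a median of 0.11, fibrotic scar and collagen matrix 0.10, pericytes and smooth muscle 0.14, lymphocytes -0.02, and ependymal cilia -0.16. Medians were -0.12 for antigen presentation, 0.08 for apoptosis, 0.06 for ferroptosis and oxidative stress, 0.04 for autophagy and lysosome, 0.05 for regeneration-associated genes, -0.15 for cholesterol synthesis, -0.07 for nuclear-encoded oxidative phosphorylation, -0.07 for immediate early genes, 0.01 for erythrocytes and 0.17 for skeletal muscle. In 8 of these lists the median, the mean of log2 fold changes, the mean difference in level and the test did not all have the same sign, namely ependymal cilia (mean difference in level 0.050), lymphocytes, oligodendrocytes, oligodendrocyte precursors, erythrocytes, stress granules, immediate early genes, and neural stem and progenitor cells.

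With 1 library left out, 14 of these 23 lists passed in at least 1 case. Without the library labelled control 3, 8 did: astrocytes (mean difference -0.214, adjusted p = 0.0024), ependymal cilia (-0.185, 0.038), homeostatic microglia (-0.221, 0.049), activated microglia and macrophages (0.216, 0.045), fibrotic scar (0.361, 0.00013), pericytes (0.442, 0.023), cholesterol synthesis (-0.166, 0.041) and skeletal muscle (0.915, 0.029). Those that passed without the library labelled control 1 were oligodendrocytes and myelin (0.203, 0.00027), ferroptosis (0.136, 0.034) and nuclear-encoded oxidative phosphorylation (-0.130, 0.0036). Antigen presentation passed without that labelled control 2 (-0.244, 0.0041) or CKO 1 (-0.287, 7.5e-05), and fibrotic scar (0.246, 0.0036) and cholesterol synthesis (-0.150, 0.041) also did without the latter. Omitting the library labelled CKO 2 let erythrocytes (-0.444, 0.00088) and skeletal muscle (0.855, 0.017) pass, omitting CKO 3 astrocytes (-0.134, 0.041), and omitting CKO 4 the integrated stress response (0.166, 0.040). Among lists that had passed with all libraries, the library labelled control 3 left out gave mean differences over 1.5 times as large for inflammatory cytokines (0.369 against 0.231), endothelial cells (0.398 against 0.253), neurons (-0.311 against -0.185) and growth inhibitors (-0.261 against -0.157).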

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

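The tests of counting noise, of cells outside the Nestin lineage, of depth and of amplification were chosen only after the results were seen.

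In 7 of 200 groups of 4 values, 1 library lay far from the other 3, where chance gives about 10. Genes with counts numbered 18884 in the library labelled control 1, below the other control libraries. Malat1 was highest in that labelled control 4, at 78.9 CPM. In the library labelled CKO 2, Ltf reached 241 CPM and the erythrocyte list 1.23 log2 units, against -0.50 to -0.38 in the other CKO libraries. Rsad2 was highest in the library labelled CKO 1, at 7.93 CPM. In that labelled CKO 4, the ribosomal protein list (0.026) and the list of the integrated stress response (-0.10) were lowest of their group.

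Tia1 in the libraries labelled control 2 and CKO 4 lay nearer the other group. Counting noise as the whole cause is argued against: the dispersion index of Tia1 counts within groups was 17.7, where counting alone gives about 1. The spread between separate samples also raises this index, so it does not say what the added spread is. Exchanged labels stay open. Over the 100 genes that best parted the other 6 libraries, these 2 libraries lay nearer the opposite group in 57% of cases, against a median of 56.5% and a range of 45.5% to 76.5% over the 15 other pairs. More cells outside the Nestin lineage in the library labelled CKO 4 stay open too: its mean over 5 lists of such cells, 0.082, lay within the -0.042 to 0.332 of the other CKO libraries, with fibrotic scar (0.55) and endothelium (0.20) above theirs, activated microglia (-0.13) below, and homeostatic microglia (-0.07) and neutrophils (-0.13) within. A biological difference in how much of the gene was removed was not tested.

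The library labelled control 1 stood apart from the other 7. Lower depth is argued against, because after thinning to its total it still had 18884 detected genes against 22236 to 23084 in the others, and a trend on GC content and length as the whole cause is argued against, because 2072 of its genes still lay over 1 log2 unit from the others after removal, against 2726 before and at most 796 in the others. A candidate explanation is few starting molecules amplified many times: genes with a median of 1 to 3 counts elsewhere had 0.98 times the usual mean there, yet 73.1% of them were at 0 counts against 18.5% to 27.99%, and those above 0 had a mean of 7.10 counts against 2.55 to 3.15. These genes were chosen by their counts in the other 7 libraries only, so part of both contrasts comes from the choice. Another mix of cell types stays open, with deviating genes 1.26 times as frequent among members of 16 cell type lists as among other genes. Genotype, the only biological difference the labels name, is shared with 3 other libraries.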

How the results depend on the processing

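The fits without libraries in doubt, with library weights, and with the GC and length trend removed were chosen after the data were seen. The count of 0 genes changed was 1 with DESeq2 (Saa3), on 28868 genes and, added after the data were seen, on those kept by filterByExpr (adjusted p = 0.023), and 0 under every other alternative to the main test, each library left out included (0 to 0). The test of exchanged labels also left out 1 control and 1 CKO library together. That gave 1 gene without control 1 and CKO 3, and 0 for every other pair. Genes at an unadjusted p under 0.05 numbered 234 and between 140 (replicate block) and 1104 (without control 3). Tia1 had a log2 fold change of -0.41 to -0.16 with each library left out. Among these fits it passed an unadjusted edgeR p of 0.05 only without control 2. That is the control library with the lowest Tia1, so its omission must enlarge the difference. The log2 fold change of Tia1 was -0.32 with library weights (limma p from a model across all genes, 0.048). The weights were estimated from these same data: 0.19 for control 1, 0.60 for control 2, 0.86 for CKO 4 and 2.49 for control 4. Control 2 and CKO 4, whose Tia1 lay nearer the other group, thus counted less than control 4, so this p is not separate support for a fall. The log2 fold change of Tia1 was -0.18 with the GC and length trend removed (unadjusted edgeR p of 0.254) and -0.18 with FPKM + 1 (limma p from a model across all genes, 0.213). The 12 lists became 7 to 19 with each library left out, 0 with an estimated correlation, 0 with fry and 7 without the libraries labelled control 2 and CKO 4. The neuronal list went from lower to higher without control 2 (0.035, and -0.311 to 0.035 over single omissions), without control 2 and CKO 4 (0.10), and without these and control 1 (0.16), where it passed as higher (adjusted p = 0.0080). With all 3 left out, lists also turned for synapses (0.023), endothelium (-0.052), proliferation (-0.049), fibrotic scar (-0.43, and -0.21 with 2 left out) and cholesterol synthesis (0.17). Apart from fewer libraries, the cause was not tested. None of the 58 single genes passed the threshold in the main test, so staying short of it says little of how stable they were. Of their 1216 alternative values, 1215 stayed short of the threshold and 18 changed sign. For the 12 lists past it, 145 of 216 kept their call, 65 lost it and 6 changed direction. For the other 23, 387 of 414 kept theirs, 24 newly passed, 3 turned and passed, and 63 changed sign. The replicate numbers gave no sign of pairing, with correlations of same-numbered deviations of -0.06, 0.05, -0.09 and -0.33, though these cannot exclude it. The replicate block gave 0 genes, 11 lists and -0.28 for Tia1. At this depth and spread, 2-fold changes were recovered in 38.0% of simulated genes. These were drawn independently and without a library that stands apart, so recovery in the real libraries may be lower.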

Other observations

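The test of other splits of the libraries was chosen only after the results were seen, while those of chromosome segments and near-identical copies were fixed before.

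Markers of tissues in and around the cord differed between libraries without regard to genotype. The skeletal muscle list stood at 2.11, 1.73 and 1.59 log2 units in the libraries labelled control 3, CKO 1 and CKO 3, and at -2.11 to -0.27 in the other 5. The erythrocyte list stood at 1.23 in that labelled CKO 2 and 0.61 in that labelled control 1. The list of ependymal cilia, of cells that line the central canal, ran from -0.74 in the library labelled control 3 to 0.88 in that labelled control 4. The fibrotic scar and collagen matrix list stood at 0.72 and 0.55 in the libraries labelled control 3 and CKO 4, and at -0.50 to 0.13 in the others.

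A search made after the data were seen found 89 genes of at least 1 CPM at 2 levels, with a gap of at least 1 log2 unit and at least 2 libraries on each side. Of these, 6 shared the split of the skeletal muscle list, and 31 of the remaining 83 were high in the libraries labelled control 3 and CKO 4 and low in the other 6. The transporter gene Slc6a13 had 48.8 and 46.0 CPM in those 2 and 10.1 to 16.9 CPM in the others, Prg4 68.0 and 98.4 against 16 to 26.0 CPM, Itih2 81.2 and 80.3 against 14.5 to 30.9 CPM, and Bnc2 9.38 and 11.6 against 1.97 to 3.85 CPM. None of the 89 genes parted the libraries by genotype.

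Other genes at 2 levels followed other libraries. Hal, the histidine ammonia-lyase gene, had 40.5, 160 and 78.7 CPM in the libraries labelled control 4, CKO 1 and CKO 2 and 0.42 to 0.89 CPM in the other 5. Gapdh had 83.6 and 163 CPM in those labelled control 2 and control 4 and 2.02 to 5.85 CPM in the other 6, and has many near-identical copies. Pcna-ps2 had 29.3 and 25.1 CPM in those labelled control 1 and CKO 4 and 1.25 to 1.86 CPM in the others. A candidate explanation is chromosome segments of different strain origin, for which pairs within 5 Mb should share a split, and 18.75% of 16 such pairs did, against 15.3% of pairs on different chromosomes (permutation p = 0.473). However, 31 of the 83 genes shared 1 split, which raises the share on different chromosomes, and only 16 pairs were close. Those 31 were high in the libraries labelled control 3 and CKO 4, which also had the highest levels of the fibrotic scar list (0.72 and 0.55). They were not removed before the test. The test can therefore not decide, and this explanation stays open. Reads shared between near-identical copies also stay open, since processed pseudogenes, Gm genes and ribosomal protein genes made 10.8% of these 83 genes against 9.10% of tested genes. Genotype, the only biological difference the labels name, parts none of them.

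Gm8730 and Rplp0 were chosen after their values were seen. In the library labelled CKO 1 alone, Gm8730 had 11960 counts against 92 to 167 in the others, while Rplp0 had 12325 against 16237 to 29854. Together they had 1366 CPM there and 1136 to 1666 CPM in the others.

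Chance could not be excluded for the count of lists. Of the 35 splits of the 8 libraries into groups of 4, 35 gave at least the 0 genes of the real split, with 1 gene in the highest other, but no split can give fewer than 0, so this decides nothing. As many lists as the 12 of the real split came from 16 of the 35 splits, with 20 in the highest other. The median of the splits was 11 lists, so the real count was near that of an arbitrary split. The real split had 234 genes at an unadjusted p under 0.05, and 32 of the splits had as many. The split with 2383 such genes set the libraries labelled control 1, control 3, CKO 2 and CKO 4 against the rest and was the highest count of the 35.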
